A study of Mus musculus with 12 samples.

How the data were processed

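Bulk RNA-seq of 3 lines of mouse embryonic fibroblasts immortalised with a papillomavirus E6 protein was analysed: wild-type lines 1 and 2 and 1 line labelled p27-null, 4 libraries each, grouped by the titles of the samples. Per the labels' protocols, cells grew for 24 h in 10% serum, and paired-end reads of 150 bp were sequenced at about 10 M reads per sample. Per the submitters' processing notes and design text, reads were checked with FastQC, aligned to GRCm39 and counted per GENCODE gene with STAR 2.5.4a. The GENCODE release, the strand setting and the filter behind the genes listed are not given in the sources used here. The deposited table holds, per the file headers, raw read counts per gene and library. It also holds the authors' CPM, which equals the count divided by the column total, and the authors' log2 CPM, which equals log2 of CPM plus 0.106. The authors also deposited their own comparison: a mean normalised signal per gene, a log2 fold change with its error, a test score, a p-value and an adjusted p-value. Its tool and direction are not given in the sources used here; from the signs against the counts, its log2 fold change is p27-null over wild type. The ratio of the mean normalised count computed here to the authors' mean signal had a median of 0.969 (10th to 90th percentile 0.871 to 1.07), and 8 of the 12 genes with 0 counts in every library had an authors' mean signal above 0.

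The table lists 15207 entries. Of these, 51 name no gene and were left out of library sizes and tests; they took 2.04 to 5.25% of a library's counts, nearly all in 1 entry (2.01 to 5.24%). Of the 15156 entries with an identifier, 15153 were found in GENCODE vM39 for GRCm39, which gave chromosomes, coordinates (counted from 1) and gene types. Counts in named genes ran from 15.4 to 24.0 M per library (mean 18.0 ± 2.18 SD, n = 12). Every library thus held more counts than the about 10 M reads per sample of the protocols, a mismatch that was not resolved here. CPM here is counts per 1 M counts in named genes, scaled by TMM factors. Duplicated libraries were looked for: within every line, counts of 2 libraries differed by more than sampling noise (chi-square per degree of freedom 10.3 to 66.6), so all 12 were kept.

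Genes were tested with edgeR 4.0.16 in R 4.3.3 on the counts, with TMM normalisation, filterByExpr and quasi-likelihood F tests, two-sided, and Benjamini-Hochberg adjustment over the 14392 genes tested at a threshold of 0.05. The libraries labelled p27-null (n = 4) were set against both wild-type lines pooled (n = 8), where the spread includes the difference between wild-type lines. A fit with 1 mean per line gave the comparisons with each wild-type line and between them, and each wild-type line was set against the other 2 lines in the way the line labelled p27-null was. The standard error of a log2 fold change is its size divided by the square root of F, an approximation. Where all libraries of a group had 0 counts, the fold is a bound against 3 counts over the group, and where a group held 1 to 3 counts only levels are given. Of 45 gene lists fixed in advance, 43 had at least 5 tested genes and were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01 and, as an alternative, an estimated correlation, with adjustment over the 43 lists. Chromosome medians were compared over 20 chromosomes with exact permutation tests of libraries, two-sided, and genes within 10 Mb of Cdkn1b with Fisher's exact test. Values shared by the comparisons with both wild-type lines were set beside 20 simulations of unchanged groups. Pseudogenes were matched to coding transcripts with blastn 2.17.0 (at least 95% identity over 150 bases). Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.

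Genes were named by a fixed rule. Cdkn1b came first. For the libraries labelled p27-null, genes passing the pooled test and the test against each wild-type line in the same direction, with all 4 libraries beyond all 8 wild-type libraries, a mean CPM of at least 5 and an official symbol gave the 8 largest increases, the 8 largest decreases and, with an absolute log2 fold change of at least 1, the 6 most abundant in each direction. Each list gave up to 4 members with the smallest adjusted p. Between the wild-type lines the 5 largest changes each way, and for each wild-type line against the rest the 3 largest each way, were taken by the same filters. Genes outside the rule are marked as chosen after their values were seen. The samples, groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined; alternatives added later are named with the sensitivity results. Alternatives were DESeq2 1.42.0, its size factors, no filter, the experiment number as a block, a 2-fold minimum, counts summed per line, limma-voom with the line as a random block, a contrast of 3 line means, other windows and filters, and each library left out in turn.

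The steps were tested on simulated data drawn from the real means and library sizes. In the pooled comparison of 14325 simulated genes, edgeR made 11 false calls among 169, and in the comparison of the wild-type lines, where nothing was changed, 0 calls. Each simulated gene had the same mean in both wild-type lines, so these figures leave out the real differences between lines. A simulated list shift of 0.5 over 14315 genes was recovered at camera adjusted p = 2.3e-48, with 0 other lists called, and a chromosome shift of 0.2 over 12000 genes at 0.183. Intervals and floors cover counting error only.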

Results

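RNA was sequenced from mouse embryonic fibroblasts immortalised with the E6 protein of a human papillomavirus, a viral protein that targets p53 for degradation. The gene of interest was Cdkn1b, which encodes p27, an inhibitor of cyclin-dependent kinases. Per the labels there were 3 lines: 2 wild-type lines (line 1 and line 2) and 1 line labelled p27-null, each sampled in 4 experiments after 24 h of growth in 10% serum. Each library held between 15.4 and 24.0 M counts in named genes, with a mean of 17.1 ± 0.960 M (SD, n = 4) for the libraries labelled p27-null, 17.7 ± 1.66 M (n = 4) for wild-type line 1 and 19.3 ± 3.17 M (n = 4) for wild-type line 2. The lines separated along the leading pair of principal components, which held 46.1% and 36.7% of the variance. The next component (7.30%) set apart the experiment 1 libraries of the line labelled p27-null and of wild-type line 1. In these 2 libraries mitochondrial genes took 1.06% and 1.33% of the counts and ribosomal protein genes 5.27% and 5.11%, against 1.74 to 3.09% and 3.24 to 4.73% in the other 10. The question was which transcripts differ in the absence of p27. Because there was 1 line of that genotype, genotype and line cannot be separated. The labels do not say that experiments were separate cultures, so p-values measure the spread between these samples, which may be technical.

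**Figure D1:**
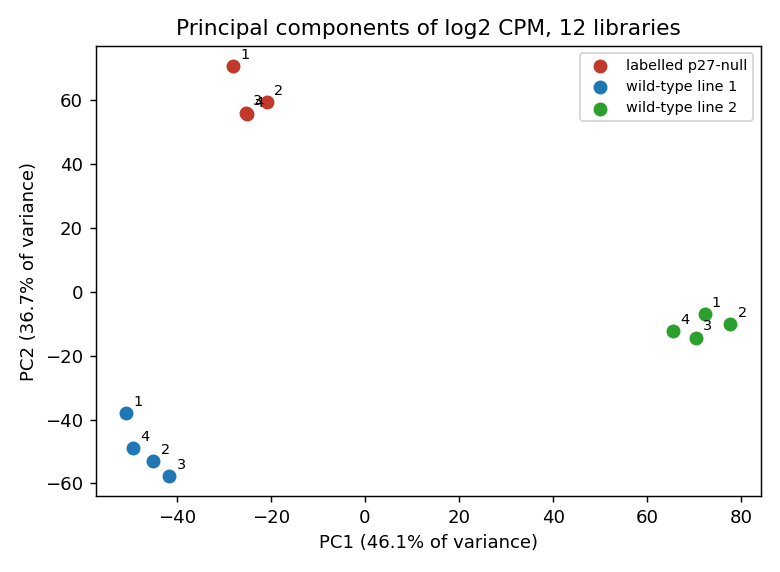
Principal components of log2 CPM in the 12 libraries, 1 point per library, coloured by line, with the percent of variance on each axis. Each line forms its own group along the leading components (46.1% and 36.7%). Component 3 (7.30%), which is not drawn, sets the experiment 1 libraries of the line labelled p27-null and of wild-type line 1 apart.

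The targeted gene was read first. Cdkn1b (chromosome 6, 134897364 to 134902476 in GRCm39) was counted at 83.7, 114, 118 and 98.2 CPM in the 4 libraries labelled p27-null, at 86.8, 89.3, 92.3 and 101 CPM in wild-type line 1 and at 92.7, 120.0, 92.9 and 88.7 CPM in wild-type line 2. The log2 fold change of 0.12 ± 0.11 (SE) did not pass the test (edgeR adjusted p = 0.499). Its canonical transcript has 4552 bases in 2 exons, of which 591 are coding and 87.0% untranslated, so a deletion of coding sequence can leave most of the counted transcript in place. The Cdkn1b counts therefore do not check the label, and the groups are called the libraries labelled p27-null and the wild-type lines throughout. The lines also differed in sex chromosome transcripts. Xist, the RNA that silences an X chromosome in female cells, was at 716 ± 249 and 739.9 ± 139 CPM (SD, n = 4 each) in wild-type lines 1 and 2 and at 0.0901 ± 0.112 CPM (n = 4) in the libraries labelled p27-null. The Y genes Ddx3y, Kdm5d, Eif2s3y and Uty were at 44.3 ± 20.8, 25.9 ± 5.46, 37.8 ± 13.0 and 20.9 ± 8.03 CPM in the libraries labelled p27-null and at no more than 0.0628 CPM on average in either wild-type line. Against wild-type line 1, with 0 counts, Ddx3y was at least 1064-fold and Uty at least 501.9-fold higher, taking 3 counts over the group as the floor. Such floors cover counting error only.

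**Figure D2:**
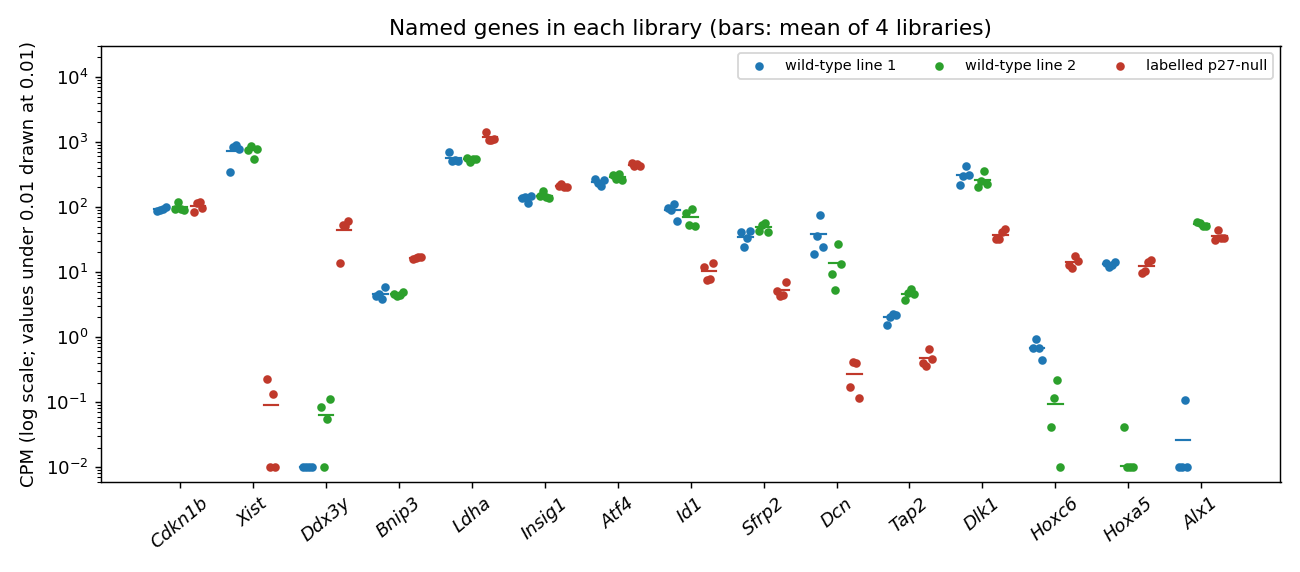
CPM of 15 named genes in each of the 12 libraries on a log axis, 1 point per library and a bar at the mean of the 4 libraries of each line; values under 0.01 are drawn at 0.01. Cdkn1b lies at similar levels in all lines, while Bnip3, Ldha, Insig1 and Atf4 lie higher and Id1, Sfrp2, Dcn, Tap2 and Dlk1 lower in the libraries labelled p27-null than in both wild-type lines.

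Against the 8 wild-type libraries, genes that rose in the libraries labelled p27-null included glycolytic, lipid synthesis and ATF4 response genes. Bnip3, a hypoxia-induced mitophagy receptor (chromosome 7, 138490690 to 138511253), rose from 4.60 ± 0.605 (SD, n = 8) to 16.7 ± 0.545 CPM (n = 4), a log2 fold change of 1.86 ± 0.11 (edgeR adjusted p = 3.0e-07). Of 25 glycolysis and hypoxia genes, 18 rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 fold change of 0.69. Phosphofructokinase Pfkl rose by 1.64 ± 0.17, aldolase Aldoa by 1.21 ± 0.11, lactate dehydrogenase Ldha by 1.09 ± 0.11 and enolase Eno1 by 1.07 ± 0.11 on the log2 scale (edgeR adjusted p between 1.4e-05 and 3.6e-05). The exception was another phosphofructokinase, Pfkp, chosen after its values were seen, at -1.72 ± 0.28 (edgeR adjusted p = 0.00108). The list passed camera (camera adjusted p = 1.9e-11; adjusted p = 0.188 with an estimated correlation). The glycolytic enzymes have processed copies in the genome that can share their reads.

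Of 24 cholesterol synthesis genes, 7 rose and none fell (8 and 0 adjusted over the list alone; median 0.31). Insig1, a sterol-regulated protein that restrains the pathway (chromosome 5, 28276315 to 28283668), was at 209.6 ± 9.51 CPM (SD, n = 4) against 143 ± 16.1 (n = 8), a log2 fold change of 0.55 ± 0.09. Srebf2, a transcription factor of the pathway, rose by 0.44 ± 0.10 (edgeR adjusted p = 0.00103 and 0.00716). Of 15 fatty acid synthesis genes, 5 rose (6 adjusted over the list alone; median 0.23), with the desaturases Scd2 at 1.12 ± 0.17 and Fads1 at 0.54 ± 0.11 (edgeR adjusted p = 0.000662 and 0.00320). The other 3 were Scd1, Agpat2 and, chosen after its values were seen, Fads2 (0.49 ± 0.15). Agpat2 lost its call without the experiment 1 library labelled p27-null, Scd1 without the experiment 3 library and Fads2 without each of 10 of the 12 libraries (edgeR adjusted p = 0.0648, 0.0538 and up to 0.138). Of 24 genes of the ATF4 and amino acid response, 6 rose and none fell (6 and 1 adjusted over the list alone; median 0.24). Atf4, the transcription factor that names the list, and its target Ddit3 rose by 0.74 ± 0.10 and 0.79 ± 0.11 (edgeR adjusted p = 0.000318 and 0.000296). Of 26 oxidative phosphorylation genes 7 rose (8 adjusted over the list alone; median 0.18), among them the ATP synthase subunit Atp5f1b (0.48 ± 0.10) and the succinate dehydrogenase subunit Sdha (0.38 ± 0.08). Only 3 of the 26 rose past the threshold against each wild-type line taken singly. Of 32 cytosolic ribosomal protein genes only Rplp0 passed the test (0.69 ± 0.13; also 1 adjusted over the list alone; median 0.15), and these genes share reads with near-identical copies. Camera called the cholesterol list (camera adjusted p = 0.00036; adjusted p = 0.864 with an estimated correlation) and, each at camera adjusted p = 0.00998, the fatty acid, ATF4, oxidative phosphorylation and ribosomal lists (adjusted p = 0.424, 0.883, 0.883 and 0.883 with an estimated correlation). Ribosomal protein genes took 5.27% of the counts in the experiment 1 library labelled p27-null and 3.86 to 4.33% in the other 3. Without that library the ATF4, oxidative phosphorylation and ribosomal lists lost their calls (camera adjusted p = 0.0825, 0.0647 and 0.234, the highest over the 12 libraries left out in turn, with lowest values of 0.000725, 0.00107 and 0.000473). The ATF4 and oxidative phosphorylation lists also lost them without both experiment 1 libraries that stood apart (0.0643 and 0.0505).

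Other groups were lower. Of 11 antigen presentation genes, 5 fell (7 adjusted over the list alone; median -0.75). Tap2, a subunit of the peptide transporter that loads MHC class I (chromosome 17, 34422501 to 34435829), fell from 3.30 ± 1.48 to 0.468 ± 0.132 CPM (SD, n = 8 and n = 4), a log2 fold change of -2.80 ± 0.41 (edgeR adjusted p = 0.000496). Its partner Tap1 was at -1.20 ± 0.27 and the class I heavy chains H2-D1 and H2-K1, near-identical genes that can share reads, at -2.10 ± 0.40 and -2.01 ± 0.55. The fifth was the class I transactivator Nlrc5, chosen after its values were seen (-2.72 ± 0.88, edgeR adjusted p = 0.0487). Of 20 imprinted growth genes, 8 fell and 1 rose, also adjusted over the list alone (median -0.62). Dlk1 (chromosome 12, 109418749 to 109429262), Rtl1 and Mirg lie in the same imprinted region of chromosome 12 and fell, at -2.93 ± 0.23, -1.74 ± 0.21 and -1.81 ± 0.18 (edgeR adjusted p = 3.8e-06, 0.000108 and 2.2e-05). The maternally expressed Igf2r rose by 0.61 ± 0.09 (edgeR adjusted p = 0.000676). Of 9 adipogenic genes, 4 fell, also adjusted over the list alone (median -1.75): the adipogenic regulator Pparg (-1.96 ± 0.32), the lipid droplet protein Plin4 (-1.96 ± 0.25), Cebpa (-0.94 ± 0.31) and Zfp423, which was at 0.0292 ± 0.0337 CPM against 3.19 ± 3.52. Of 19 Wnt signalling genes, 6 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.76). The Wnt agonist Rspo2 (chromosome 15, 42877439 to 43034706) fell, at -2.43 ± 0.16, the antagonists Sfrp2 and Dkk2 at -3.00 ± 0.24 and -2.46 ± 0.29 and the receptor Fzd1 at -0.76 ± 0.12 (edgeR adjusted p = 6.8e-07, 4.6e-06, 7.8e-05 and 0.000796). The member that rose was Lef1, a transcription factor of the pathway, chosen after its values were seen (1.29 ± 0.25). With 1 library left out at a time, H2-K1, Nlrc5, Cebpa and Zfp423 lost their calls in 3, 8, 9 and 4 cases (edgeR adjusted p up to 0.0780, 0.128, 0.138 and 0.0828). Camera called the antigen presentation, imprinted, adipogenic and Wnt lists (camera adjusted p = 0.00998, 0.0104, 0.0184 and 0.0328; adjusted p = 0.237, 0.757, 0.237 and 0.398 with an estimated correlation). The Wnt list lost its call without the experiment 3 library labelled p27-null (camera adjusted p = 0.0524, the highest of 12 such values, the lowest being 0.0178) and in a fit with 1 mean per line (0.0779). Without the 2 experiment 1 libraries that stood apart the Wnt, imprinted and adipogenic lists all lost theirs (0.0561, 0.0505 and 0.0582).

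Of 20 Hox genes tested, 5 rose, also adjusted over the list alone (median 0.53; camera adjusted p = 0.00036; adjusted p = 0.883 with an estimated correlation). They were Hoxc4, Hoxc5, Hoxc6, Hoxc8 and, chosen after its values were seen, Hoxa9 (3.55 ± 0.82). Hoxc6 (chromosome 15, 102906689 to 102920315), a regulator of position along the body axis, was at 14.2 ± 2.62 CPM (SD, n = 4) against 0.688 ± 0.208 and 0.0942 ± 0.0969 CPM in wild-type lines 1 and 2. The log2 fold change was 5.17 ± 0.58 for Hoxc6, 5.47 ± 0.57 for Hoxc4, 5.47 ± 0.67 for Hoxc5 and 3.10 ± 0.61 for Hoxc8 (edgeR adjusted p = 5.9e-05, 3.4e-05, 0.000117 and 0.00345). The list as a whole followed the wild-type line used: against wild-type line 1 alone 5 members rose and 8 fell, with a median of -0.47 (camera adjusted p = 0.407).

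Lists tied to the known roles of p27 in the cell cycle, autophagy and mTORC1 signalling moved as groups in no direction that passed camera. Among 18 CDK inhibitors and G1 cyclins only Cdk4, a kinase of G1, rose (0.42 ± 0.09, edgeR adjusted p = 0.00603; also 1 adjusted over the list alone; camera adjusted p = 0.784). Of 33 E2F and S phase genes 3 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.709). The replication clamp Pcna rose by 0.51 ± 0.09 and thymidylate synthase Tyms fell, at -0.27 ± 0.06 (edgeR adjusted p = 0.00132 and 0.00651). The others were Dut (0.54 ± 0.13), Gins2 (-0.36 ± 0.09) and, chosen after their values were seen, Pole (0.20 ± 0.07), Chaf1b (-0.42 ± 0.12) and Rfc3 (-0.34 ± 0.11). Of 29 G2 and mitosis genes 4 rose, also adjusted over the list alone (camera adjusted p = 0.907): Ccnb1 (0.30 ± 0.08), Mybl2 (0.51 ± 0.15), Aurka (0.32 ± 0.09) and Ube2c (0.37 ± 0.11), with edgeR adjusted p between 0.0267 and 0.0400. Single libraries carried several of these calls. With each of the 12 left out in turn, Ccnb1, Mybl2, Aurka and Ube2c lost theirs in 3, 5, 3 and 9 cases (edgeR adjusted p up to 0.0628, 0.121, 0.103 and 0.122), and Dut, Gins2, Pole, Chaf1b and Rfc3 in 1, 3, 12, 5 and 8 (up to 0.0517, 0.107, 0.135, 0.114 and 0.161). Pcna, Mybl2, Aurka, Ube2c and Dut lie on chromosome 2, whose genes had a median log2 fold change of 0.19. Of 31 autophagy genes, Uvrag (0.53 ± 0.10) and Atg14 (0.61 ± 0.12), both subunits of lipid kinase complexes that act in autophagy, rose and the cargo receptor Optn fell (-1.19 ± 0.29), also adjusted over the list alone (camera adjusted p = 0.773). Of 27 mTORC1 genes, 5 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.130). Rragb, a Rag GTPase gene on the X chromosome, fell, at -1.99 ± 0.23 (edgeR adjusted p = 7.6e-05). The Rag GTPase gene Rragc (0.41 ± 0.09), the mTORC1 inhibitor Tsc1 (0.53 ± 0.09), Akt1s1 (0.32 ± 0.09) and, chosen after their values were seen, Deptor (0.76 ± 0.25) and Sesn2 (0.65 ± 0.20) rose. Of these, Akt1s1, Deptor and Sesn2 lost their calls in 5, 10 and 7 of the 12 cases (edgeR adjusted p up to 0.1002, 0.155 and 0.138). Of 33 lysosome genes, 6 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.176), with the proton pump subunit Atp6v1a at 0.62 ± 0.10, cathepsin Ctsf lower (1.16 ± 0.250 against 4.66 ± 1.68 CPM, edgeR adjusted p = 0.000688) and the transcription factor Mitf at -1.74 ± 0.28.

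Gene by gene, the largest increase among autosomal genes named here was in the homeobox gene Meox1 (chromosome 11, 101768336 to 101785227), at 32.8 ± 10.6 CPM against 0.330 ± 0.213 (6.59 ± 0.39, edgeR adjusted p = 2.7e-07). Other large increases named by the rule were in Plac8 (5.11 ± 0.76), the long noncoding RNA AI506816 (4.63 ± 0.11) and the potassium channel Kcnj15 (3.75 ± 0.29; edgeR adjusted p = 0.000525, 7.0e-11 and 2.8e-06). The noncoding RNA Hdnr, the glycosyltransferase Galnt14, Cpxm2 and the matrix protein Prelp had 0 counts in all 4 libraries labelled p27-null. They were at least 58.0-fold, 16.9-fold, 32.9-fold and 43.8-fold lower than in wild-type line 1 and, because line 2 held more of them, at least 1009-fold, 758.4-fold, 338.4-fold and 297.2-fold lower than in line 2. The limits of Prelp rested on 1 library each: without the highest library of a line they were 17.7-fold and 147.9-fold, and that of Galnt14 in line 2 was 571-fold. Galnt14 lost its call without any of the 4 libraries labelled p27-null (edgeR adjusted p between 0.0599 and 0.0631). The RNase P RNA-like Rprl3 fell, at -9.86 ± 0.48 from 75.9 ± 24.2 CPM, an uncertain value because such copies can share reads. Among abundant genes the interleukin 33 receptor Il1rl1 rose to 1312 ± 399 CPM and the actin-severing protein gelsolin, Gsn, to 893 ± 177 CPM (1.24 ± 0.29 and 1.35 ± 0.16). In contrast, collagen Col12a1, cadherin Cdh11, Aplp2 and the protease Mmp2 fell (-1.72 ± 0.29, -1.30 ± 0.23, -1.07 ± 0.14 and -1.15 ± 0.24). In the genes of this comparison listed as rising or falling, all 4 libraries labelled p27-null lay beyond all 8 wild-type libraries, except in Akt1s1, Ccnb1, Cebpa, Chaf1b, Deptor, Dut, Fads2, Mybl2, Nlrc5, Scd1, Sesn2, Tap1, Ube2c and Zfp423. In total 2700 of 14392 genes passed the test, 1219 higher and 1481 lower, and 280 and 859 of these changed at least 2-fold. The 4 libraries lay above all 8 others in 946 genes and below them in 1050, whereas 2463 genes parted wild-type line 1 and 2894 parted line 2 from the rest in this way, so such a separation is ordinary between these lines. The spread behind these p-values is between libraries: with counts summed per line, which leaves 1 value against 2, edgeR called 0 genes (608 at an unadjusted p under 0.05). With the line as a random block limma-voom called 230. None of the camera calls held with an estimated correlation, and other splits of the 12 libraries called up to 19 lists, against 11 here. In the comparison deposited by the authors 4656 genes had an adjusted p under 0.05. Of the 2700 genes, 2691 were among them with the same sign. The log2 fold changes correlated across 14392 genes, which are not independent replicates, with r = 0.993.

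**Figure D3:**
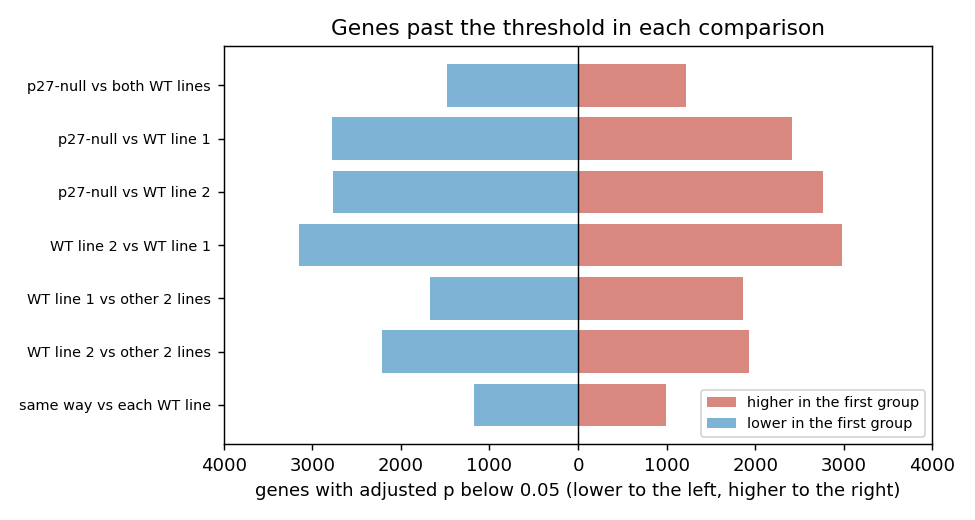
Number of genes passing the edgeR test (adjusted p under 0.05) in each comparison, higher and lower drawn as separate bars from 0. The comparison between the wild-type lines holds 6133 genes and that of the libraries labelled p27-null with both wild-type lines pooled 2700. The pooled tests count the difference between the pooled lines as spread, so bars of pooled and single-line comparisons are not like for like.

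Against wild-type line 1 alone, the libraries labelled p27-null showed large differences in single genes of patterning and cartilage. Zic1 and Nkx3-2, transcription factors of axial skeleton development, had 0 counts in the libraries labelled p27-null and were at 33.7 ± 0.782 and 15.7 ± 2.73 CPM (SD, n = 4) in line 1, at least 751.9-fold and 350.2-fold lower. Pax3, a regulator of muscle and neural crest precursors chosen after its values were seen, was at 69.7 ± 14.1 CPM against 0.138 ± 0.105, and the craniofacial homeobox gene Alx1 at 35.3 ± 5.68 against 0.0266 ± 0.0531. The cartilage collagen Col2a1 was at 0.0907 ± 0.0380 CPM against 46.4 ± 20.03 (-8.91 ± 0.44, edgeR adjusted p = 1.1e-08) and the cartilage proteoglycan Acan at -4.15 ± 0.70 (edgeR adjusted p = 0.000440). In total 5192 of 14392 genes passed the test, 2417 higher and 2775 lower, 1758 of them at least 2-fold. Camera called 7 lists. Higher were glycolysis and hypoxia (18 up, 2 down, median 0.79; camera adjusted p = 7.6e-09; adjusted p = 0.340 with an estimated correlation), cholesterol synthesis (14 up; 0.000215; adjusted p = 0.739 with an estimated correlation) and oxidative phosphorylation (12 up; 0.00113; adjusted p = 0.739 with an estimated correlation). Lower were the imprinted (11 down, 1 up; camera adjusted p = 0.00136), adipogenic (6 down; 0.00366), antigen presentation (5 down; 0.00782) and chondrogenic lists (6 down, 1 up; 0.00832), with adjusted p = 0.446, 0.340, 0.622 and 0.340 with an estimated correlation.

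Against wild-type line 2, Hox genes set the libraries labelled p27-null apart. Of 20 Hox genes 19 were higher and none lower, with a median of 7.35, or 6.59 with genes at 0 counts set to their bound (camera adjusted p = 2.9e-22; adjusted p = 0.0681 with an estimated correlation). Hoxa7 (chromosome 6, 52191471 to 52198834) had 0 counts in line 2 and was at 18.1 ± 3.47 CPM (SD, n = 4) in the libraries labelled p27-null, at least 466.4-fold higher, and Hoxa5 was at 12.5 ± 2.76 against 0.0104 ± 0.0207 CPM. Lower in the libraries labelled p27-null were the leptin receptor Lepr (-4.84 ± 0.48), the laminin Lama4 (-5.69 ± 0.43), the complement gene C3 (-7.80 ± 0.54) and the matrix protein tenascin N, Tnn (-7.06 ± 0.43; edgeR adjusted p = 3.9e-06, 3.3e-07, 1.6e-07 and 4.9e-08). In total 5524 genes passed the test, 2760 higher and 2764 lower, 1924 of them at least 2-fold. Glycolysis and hypoxia genes were again higher (20 up, 1 down, median 0.77; camera adjusted p = 9.9e-08; adjusted p = 0.534 with an estimated correlation). So were p53 targets (15 up, 2 down, median 0.60; camera adjusted p = 0.00122; adjusted p = 0.534 with an estimated correlation). Among them the apoptosis effector Bax was at 0.96 ± 0.14 and, against the direction of the list, the cytokine Gdf15 at -4.17 ± 0.45 (edgeR adjusted p = 0.000111 and 8.7e-06). Camera called 3 lists against line 2, all higher: the Hox, glycolysis and p53 lists. The cholesterol synthesis, oxidative phosphorylation, imprinted, adipogenic, antigen presentation and chondrogenic lists, called against line 1, did not pass against line 2.

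**Figure D4:**
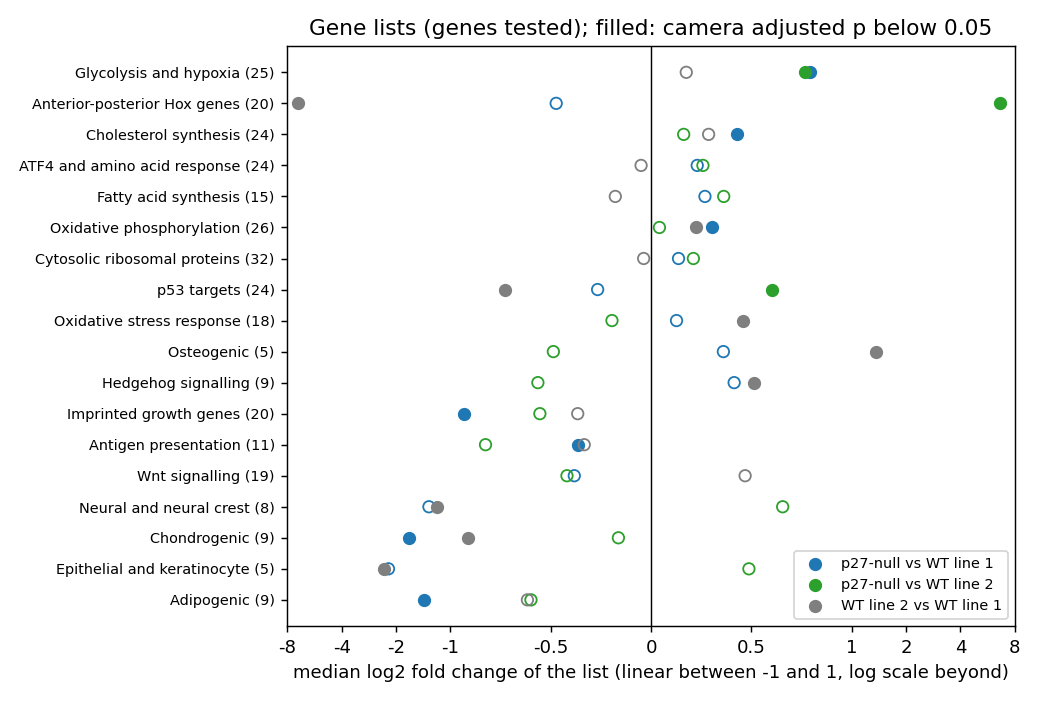
Median log2 fold change of 18 gene lists, with genes at 0 counts in a line set to their bound, for the libraries labelled p27-null against wild-type line 1, against wild-type line 2, and for line 2 against line 1; the axis is linear from -1 to 1 and logarithmic beyond, and filled points passed camera with a preset correlation. Glycolysis and hypoxia genes lie at 0.79 and 0.77 against the 2 wild-type lines, while Hox genes differ between them (-0.47 and 6.59).

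Genes that moved the same way against both wild-type lines were counted next. Bnip3 rose by 1.85 ± 0.13 against line 1 and 1.87 ± 0.13 against line 2, Ldha by 1.06 ± 0.13 and 1.12 ± 0.13 and Emx2, a homeobox gene, by 2.18 ± 0.13 and 2.04 ± 0.12. Rspo2 fell, at -2.41 ± 0.17 and -2.45 ± 0.17, Dlk1 at -3.07 ± 0.23 and -2.78 ± 0.22 and the forkhead gene Foxf1 at -3.45 ± 0.20 and -3.37 ± 0.20. In all, 2165 genes passed both tests in the same direction, 991 higher and 1174 lower; 1370 of them were not called between the wild-type lines. Counted in this way, each wild-type line set against the other 2 lines gave more, 2782 genes for line 1 and 3081 for line 2. Independent lists of these sizes would share 463.5 and 532.9. Both comparisons used the same 4 libraries labelled p27-null, which adds correlation with no effect at all: 20 simulations of unchanged groups gave 0 shared genes, a correlation across genes of 0.509 and a covariance of 0.0236, against an observed 0.446 and 0.574. The covariance beyond the simulated value was 0.550. The simulated lines had equal means, so this excess includes any difference of the shared line from the others, whatever its cause. The libraries labelled p27-null were also split by experiment, so that no library served both comparisons, though the line did. Then 1424 or 1445 genes moved the same way, and the covariance was 0.566 or 0.603. The covariance with a wild-type line in the shared place was not computed. Another 637 genes passed both tests in opposite directions, among them Lepr (5.68 ± 0.82 and -4.84 ± 0.48) and the keratin Krt19, chosen after its values were seen (-2.21 ± 0.29 and 4.78 ± 0.43).

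The wild-type lines differed from each other in Hox transcripts. Relative to line 1, all 20 Hox genes were lower in line 2 (median -7.42, or -7.01 with genes at 0 counts set to their bound; camera adjusted p = 1.2e-19; adjusted p = 0.101 with an estimated correlation). Hoxa7 was at 15.8 ± 2.77 CPM (SD, n = 4) in line 1, at least 407.5-fold above line 2, and Zic1, Nkx3-2, Hoxa5 and Zdbf2 were at 33.7 ± 0.782, 15.7 ± 2.73, 13.2 ± 0.995 and 20.8 ± 7.14 CPM against 0.0138 ± 0.0277, 0.0143 ± 0.0286, 0.0104 ± 0.0207 and 0.0284 ± 0.0328. Higher in line 2 were Alx1 (54.2 ± 3.95 against 0.0266 ± 0.0531 CPM), Lepr (10.52 ± 0.73), the homeobox gene Lhx8 (9.93 ± 0.25), the amino acid transporter Slc7a8 (19.5 ± 6.42 against 0.0133 ± 0.0266 CPM) and Tnn (9.28 ± 0.52; edgeR adjusted p = 1.4e-07, 2.4e-11 and 2.0e-08 for Lepr, Lhx8 and Tnn). In each of these genes all 4 libraries of a line lay beyond all 4 of the other. Of p53 targets, 18 were lower and 1 higher in line 2 (median -0.73; camera adjusted p = 3.8e-06; adjusted p = 0.144 with an estimated correlation). The cartilage list (5 lower, 1 higher), the neural and neural crest list (5 lower) and the epithelial list (4 lower, 1 higher) were lower in line 2, each at camera adjusted p = 0.0265 (adjusted p = 0.144, 0.144 and 0.312 with an estimated correlation). Hedgehog genes (7 higher; camera adjusted p = 0.00700), osteogenic genes (4 higher, 1 lower; 0.0332), oxidative phosphorylation genes (5 higher, 1 lower; 0.0465) and oxidative stress genes (11 higher, 3 lower; 0.0465) were higher, with adjusted p = 0.144, 0.150, 0.969 and 0.680 with an estimated correlation. Without the experiment 1 libraries that stood apart, 1 of them from line 1, the 9 calls fell to 4: Hox genes, p53 targets, Hedgehog genes and oxidative phosphorylation genes stayed. The cartilage (camera adjusted p = 0.0565), neural and neural crest (0.0523), epithelial (0.0643), osteogenic (0.0957) and oxidative stress (0.0730) lists lost theirs. Of 29 limb and positional transcription factors 11 were higher and 12 lower in line 2, and the list did not pass (camera adjusted p = 0.931). In total 6133 of 14392 genes passed the test, 2981 higher and 3152 lower in line 2, and 2001 of these changed at least 2-fold.

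Each wild-type line was also set against the other 2 lines, as the line labelled p27-null had been. Line 1 stood apart by higher Zic1, Nkx3-2 and Esm1, an endothelial proteoglycan (26.5 ± 9.08 CPM against 0.0388 ± 0.0268 in line 2 and 0.0164 ± 0.0327 in the libraries labelled p27-null), and by lower Alx1, Lepr and Vat1l (0.217 ± 0.0865 CPM against 96.4 ± 19.8 and 159.8 ± 47.1). Line 2 stood apart by higher Lhx8 (101 ± 6.99 CPM against 0.0943 ± 0.0693 and 0.0164 ± 0.0327), Hand2os1 and AI606473 and by lower Hoxa7, Hoxa5 and the cadherin Cdh10 (0.0425 ± 0.0541 CPM against 14.5 ± 1.83 and 23.2 ± 8.70). Hand2os1 is transcribed antisense to Hand2, and without a stated strand setting its value of 58.7 ± 14.9 CPM in line 2 is uncertain. With the same test of 4 against 8 libraries, 3529 genes set line 1 apart (1863 higher, 1666 lower) and 4143 set line 2 apart (1929 higher, 2214 lower). Both counts lie above the 2700 of the libraries labelled p27-null.

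Medians over the genes of a chromosome also differed between lines. Against wild type, genes on chromosome 2 were higher in the libraries labelled p27-null, with a median log2 fold change of 0.19. On this chromosome 24.7% of the tested genes moved the same way against both lines, 207 higher and 65 lower, against 15.0% of all tested genes. The share was nearly as high on chromosome 14 (23.8%, 94 higher and 23 lower), whose median did not pass (exact permutation adjusted p = 0.108). The medians of chromosomes 10 and 19 were also higher (0.03 and 0.07) and those of chromosomes 6, 17 and 18 lower (-0.15, -0.11 and -0.15), each of the 6 at exact permutation adjusted p = 0.0404; the smallest p that 4 against 8 libraries allow is 0.00202. In bins of 20 Mb the shift was not uniform on chromosome 10, where 4 of 7 bins were higher and 3 lower, nor on 19 (2 of 3 higher), while all bins of 2, 6, 17 and 18 went the way of their chromosome. Among genes with a mean of at least 5 CPM only chromosomes 2 and 10 kept their calls (exact adjusted p = 0.0135 each), 13 passed as well, and 19, 6, 17 and 18 lost theirs (0.0606, 0.0970, 0.202 and 0.136). With the trend with GC content removed, the difference of library medians went from -0.128 to -0.0878 for chromosome 6, from -0.0940 to -0.0920 for 17 and from -0.119 to -0.0713 for 18, and these 3 lost their calls (exact adjusted p = 0.0741, 0.0646 and 0.0943). For chromosome 17 the size was nearly unchanged, so its lost call does not speak for GC bias. Between the wild-type lines 15 of 20 chromosomes differed (exact adjusted p = 0.0381), with medians of -0.40 for chromosome 7, 0.36 for 14, 0.31 for 16, -0.29 for 8 and -0.28 for 11. Against line 2 the libraries labelled p27-null differed on 13 chromosomes (exact adjusted p = 0.0440), led by chromosome 7 at 0.25 and the X chromosome at -0.24. The X chromosome median was -0.279 in the experiment 1 library labelled p27-null and -0.0349 to 0.00256 in the rest of its line, so 1 library enlarged that shift. The same library lay lowest of its line on chromosomes 6 (-0.169 against -0.0813 to -0.0103) and 18 (-0.161 against -0.0510 to -0.00165). Against line 1 no chromosome passed, with an exact adjusted p of 0.0635 at best. The smallest exact p that 4 against 4 libraries allow is 0.0286, so whether any chromosome passes after adjustment depends on how many reach it. Too few did against line 1, which does not show that no chromosome shifted. The largest medians were 0.42 for chromosome 14, -0.28 for 8 and 0.24 for 12.

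**Figure D5:**
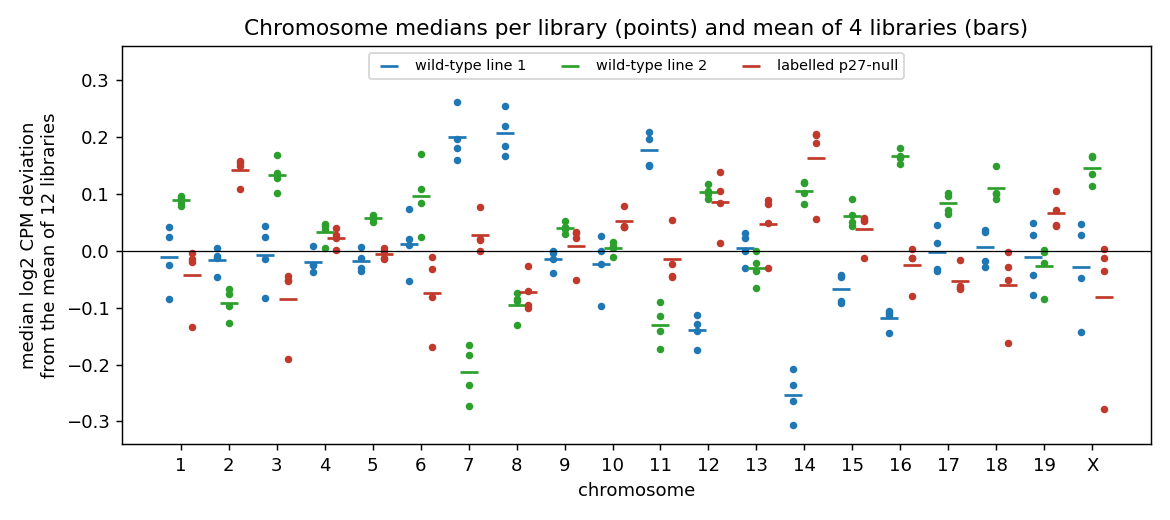
Median over each chromosome's genes of log2 CPM minus the mean of the 12 libraries, 1 point per library, for the 20 chromosomes tested, coloured by line. Libraries of a line lie close together on most chromosomes, and the experiment 1 library labelled p27-null lies apart from its line on the X chromosome at -0.28.

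The last comparison concerned genes around Cdkn1b, since a targeted allele can carry flanking sequence of another strain. Within 10 Mb, Magohb, a splicing factor of the exon junction complex, fell, at -0.65 ± 0.13 and the orphan receptor Gpr19 at -0.58 ± 0.13, while Arhgdib rose by 0.96 ± 0.24 (edgeR adjusted p = 0.00369, 0.00800 and 0.0128). In the comparison with wild type 23 of the 98 tested genes in this window passed, or 23.5%, against 18.7% of all other genes (odds ratio 1.33, 95% interval 0.794 to 2.15; two-sided Fisher's exact p = 0.242). Between the wild-type lines it was 38 of 98 (odds ratio 0.852, 95% interval 0.551 to 1.30; Fisher's exact p = 0.474). Neither share differed from the rest of the genome by more than this test allows.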

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

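The tests of differences between lines, of the share of X and Y genes and of chromosome copies were chosen only after the results were seen, as was the reading of the GC test for the pooled shifts, and the removal of the GC trend was added after the data were seen. The number of genes that set the libraries labelled p27-null apart, 2700, was weighed first. The 100 splits of the 12 libraries held the 3 that set a whole line apart and 97 drawn ones that mix lines. As many genes as for the libraries labelled p27-null (2700) were called in 3 of the 100, the highest other being 4143, as for wild-type line 1 (3529) in 2, the highest other again 4143, and as for line 2 (4143) in 1, the highest other 3529. As many genes as the 2165 that moved the same way were found in 3 of 100, the highest other being 3081. In the comparisons of 2 lines (5192, 5524 and 6133) it was 1 of 35, the highest other being 0. Mixed splits called 0 genes, and every split that called as many set a whole line apart. A mixed split puts lines that differ in 5192 to 6133 genes into the same group, which widens the spread. Such splits could hardly call any gene, so these counts of splits do not decide on chance. Genes on X and Y held 3.07% of the calls, 79 on X and 4 on Y. Only 489 tested genes lie on X and 5 on Y, too few to hold most of the 2700 calls. This share therefore cannot decide on sex as a cause. Differences between lines with no link to genotype stay open, since with 1 line labelled p27-null the genotype and the line cannot be told apart. The smaller count that sets a wild-type line apart is 3529, above 2700. These counts are not strictly like for like, because the difference between the 2 pooled lines enters the spread of each test. The pair pooled behind the 2700 differed in 6133 genes, and the pairs behind 3529 and 4143 in 5524 and 5192. An effect of the absence of p27, and of sex on autosomal genes, stay open as untested. For the gene lists chance cannot be excluded, because 20 of 100 splits called as many lists as the real 11, and the highest other called 19. The drawn splits hold uneven numbers of libraries from the 3 lines, and a count of lists does not weigh any single list.

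Shifts of chromosome medians between lines were weighed next. The 28 shifts called against wild-type line 2 or between the wild-type lines, on 18 chromosomes, had a mean size of 0.175 on the log2 scale. GC content is argued against as the whole cause of these, because 94.3% of that size was left after the trend of each library was removed and all 28 were still called. Removing it shortened 4 of them to under 75%, all against line 2, at the lowest to 63.8% for the X chromosome (-0.226 to -0.144), with chromosome 1 going from -0.132 to -0.0840. Of the 6 pooled shifts it is argued against for chromosomes 2, 10 and 19, still called with at least 105% left, and stays open for 6 and 18, which lost their calls with as little as 60.0% left; 17 lost its call at a nearly unchanged size (-0.0940 to -0.0920). A different number of chromosome copies stays open: 187 of 199 bins of 20 Mb, or 94.0%, moved in the direction of their chromosome, but these chromosomes were chosen by their shift, which largely fixes that share. The copy number of the lines was not measured here.

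Samples far from the others of their line were found in 22 of 160 groups of 4 libraries, where chance gives about 1 in 20. In the experiment 1 library labelled p27-null 5.25% of the counts lay in rows without a gene identifier, against 3.23 to 3.51% in the other 3, and Ldha was at 1437 CPM. That library also deviated in its chromosome medians, at -0.134 for chromosome 1, 0.108 for 2, -0.190 for 3, -0.0508 for 9, 0.0560 for 14, -0.0170 for 17 and -0.279 for X. The experiment 2 library labelled p27-null did so for chromosomes 10 (0.0779) and 15 (-0.0121). Ldha was at 694 CPM in the experiment 1 library of wild-type line 1, and Hdnr at 3.67 CPM in its experiment 2 library. In wild-type line 2 the experiment 1 library had 4.73% of its counts in ribosomal protein genes. The experiment 2 library of that line had 14774 genes above 0 against 14847 to 14855 in the others, with Cdkn1b at 120.0 CPM and Eno1 at 1079 CPM. The experiment 3 library had Galnt14 at 59.2, Prelp at 33.4, Mmp2 at 243, Tnn at 116 and AI606473 at 26.3 CPM.

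Effects that differed between the wild-type lines were found for 637 genes called in opposite directions against the 2 lines. All of them were also called between the lines. That was largely given in advance, since 2 differences in opposite directions add up to the difference between the wild-type lines. By the direct test of the difference, 7 lists differed and lay in opposite directions against the 2 lines: Hox genes (camera adjusted p = 1.2e-19), p53 targets (3.8e-06), Hedgehog signalling (0.00700), neural and neural crest genes (0.0265), epithelial genes (0.0265), osteogenic genes (0.0332) and oxidative stress genes (0.0465). None held with an estimated correlation (adjusted p = 0.101, 0.144, 0.144, 0.144, 0.312, 0.150 and 0.680). Without the experiment 1 libraries that stood apart, the neural and neural crest (camera adjusted p = 0.0523), epithelial (0.0643), osteogenic (0.0957) and oxidative stress (0.0730) lists lost the call. Chondrogenic genes and oxidative phosphorylation genes passed the same test (camera adjusted p = 0.0265 and 0.0465; adjusted p = 0.144 and 0.969 with an estimated correlation), with the same direction against both lines; without these libraries chondrogenic genes did not pass (0.0565). Rows without a gene identifier took 3.81% of the counts on average in the libraries labelled p27-null, with 5.25% in the experiment 1 library, and 2.70% in wild type. The difference did not pass after adjustment (exact permutation p = 0.0364, adjusted p = 0.175). Against line 1 alone the exact permutation p was 0.257. Against line 2 alone, at 2.41%, it was 0.0286, the smallest that 4 against 4 libraries allow (adjusted p = 0.171).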

How the results depend on the processing

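The alternatives without the 2 experiment 1 libraries that stood apart, without genes on X and Y, with protein-coding genes only and with the GC trend removed, and the libraries left out in turn for chromosomes and for genes near Cdkn1b, were chosen after the data were seen. DESeq2's test or size factors, no filter, genes on X and Y left out and protein-coding genes only kept each of the 7 gene counts within 1.5 times its value; for the pooled comparison they gave 3430, 2709, 2736, 2649 and 2434 against 2700. Requiring at least a 2-fold change left, by construction, 1139 of 2700 genes (pooled), 1758 and 1924 against lines 1 and 2, 2001 between the wild-type lines, 1130 and 1436 for each wild-type line against the rest and 791 moving the same way. Summing counts per line left 1 value against 2 and edgeR 0 calls (608 at an unadjusted p under 0.05). Limma-voom with the line as a block (correlation 0.509) called 230 (1589 unadjusted). The contrast of 3 line means, whose spread leaves out the difference between wild-type lines, called 4871, all 2700 included. With the libraries labelled p27-null split, 1424 or 1445 genes moved the same way; fewer samples entered each comparison. Leaving out 1 library gave 1862 to 2942 genes (pooled), 4392 to 5518 and 4653 to 5749 (against lines 1 and 2), 5342 to 6770 (between wild-type lines), 2452 to 3905 and 2808 to 4545 (each wild-type line against the rest) and 1854 to 2319 (same way). Lists called fell from 11 to 0 with an estimated correlation and to 6 without the experiment 1 libraries that stood apart (from 9 to 4 between the wild-type lines), and ran from 8 to 12 with 1 library left out; the cause was not tested. The odds ratio near Cdkn1b ran from 1.16 to 1.56 for the libraries labelled p27-null with 1 library left out. Between the wild-type lines it was 1.01 in a 5 Mb window and ran from 0.732 to 1.01, above 1 without the experiment 1 library of line 2, against 0.852; no interval excluded 1 and the cause was not tested. Chromosomes called fell from 6 to 3 for genes with a mean CPM of at least 5, which kept 2 of the 6. The cause was not tested. Against line 1 they rose from 0 to 14 with the GC trend removed. There the exact p cannot go below 0.0286, so calls after adjustment depend on how many chromosomes reach it. For chromosome 14, the largest shift, the difference of library medians went from 0.417 to 0.448 and the exact adjusted p from 0.0635 to 0.0408. The 211 values of genes under the naming rule or in the text had 4483 alternatives. Of these, 3958 left the outcome of the test unchanged, 525 lost the call and 0 reversed it. In 165 of the 211 values at least 1 alternative lost the call. Counts summed per line called 0 genes, so each named gene called in the pooled comparison lost its call there by construction. The 165 values therefore do not measure how firm single calls are. Of 364 alternatives of chromosome shifts, 355 counted as the same and 9 lost the call. Shifts were tested again with the CPM filter and with the GC trend removed. With a library left out they were not tested again. There, the same means that the shift moved by less than the larger SD of library medians of the 2 groups. Leaving out 1 library cannot move a group mean by as much as the SD of that group. These alternatives were therefore bound to count as the same and test nothing. The 9 lost calls all arose with the CPM filter or with the GC trend removed. The experiment numbers did not meet the rule for pairing, that every correlation of same-numbered deviations lies over 0.1, since these ran from 0.0421 to 0.750. In 15 of 24 combinations, not all, a library correlated best with its own number, a hint from the data and not from the design. As a replicate block they gave 2503 genes in the pooled comparison, 11 lists, the same as without, and no count moved by over 1.5 times. On simulated counts the pooled comparison recovered 53.7% of 1.5-fold, 83.6% of 2-fold and 100% of 4-fold changes. The simulated wild-type lines did not differ, while 6133 genes differed between the real ones. These shares therefore do not describe the real pooled test.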

Other observations

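The tests of low counts of pseudogenes below were chosen only after the result was seen. Several genes tied to BMP and TGF-beta signalling were lower in the libraries labelled p27-null. Id1, Id2 and Id3, which block the DNA binding of basic helix-loop-helix factors and are induced by BMP signals, fell, at -2.97 ± 0.28, -2.99 ± 0.33 and -1.22 ± 0.16 on the log2 scale (SE). Their means went from 79.8 ± 22.7, 51.3 ± 14.7 and 155 ± 24.4 CPM (SD, n = 8) to 10.2 ± 3.05, 6.45 ± 3.09 and 66.5 ± 15.3 CPM (n = 4; edgeR adjusted p = 1.6e-05, 5.0e-05 and 0.000198). The inhibitory Smad6 fell, at -1.95 ± 0.23 and the co-receptor endoglin, Eng, at -3.13 ± 0.25 (edgeR adjusted p = 8.3e-05 and 3.9e-06). Eng is on the list of endothelial genes, where other members also fell, and not on the TGF-beta response list. No list of BMP genes was fixed in advance. Id1 and Eng lie on chromosome 2, whose median log2 fold change was 0.19. Of 20 genes of the TGF-beta response list 7 fell and 1 rose, Lrrc32, chosen after its values were seen (1.44 ± 0.19). Adjusted over the list alone 7 fell and 2 rose, and the list did not pass camera (camera adjusted p = 0.162). Of 23 immediate early genes 4 fell, also adjusted over the list alone (camera adjusted p = 0.364): Fos (-1.31 ± 0.19), Egr1 (-1.03 ± 0.20), Egr3 (-1.80 ± 0.22) and Klf4 (-0.98 ± 0.25), which lost its call without the experiment 1 library labelled p27-null (edgeR adjusted p = 0.0566). Of 9 Hedgehog signalling genes the effector Gli2 fell (-0.84 ± 0.11) and Gli1, a target of the pathway, rose (1.44 ± 0.44; 1 and 2 adjusted over the list alone; camera adjusted p = 0.898). Gli1 lost its call in 7 of 12 cases with 1 library left out (edgeR adjusted p = 0.0383, up to 0.120). The Notch modifier Lfng (-1.49 ± 0.19), the chemokine Cxcl1 (-1.89 ± 0.24) and the antioxidant enzyme Nqo1 (-2.82 ± 0.59) were lower too (edgeR adjusted p = 0.000135, 0.000150 and 0.00509, and 0.000248 for Gli2).

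Matrix and adhesion genes moved both ways. The small proteoglycan Dcn fell from 26.04 ± 21.8 CPM (SD, n = 8) to 0.274 ± 0.152 CPM (n = 4), a log2 fold change of -6.55 ± 0.87 (edgeR adjusted p = 0.000224). Of 32 matrix genes 6 fell and 1 rose, Thbs2, chosen after its values were seen (1.36 ± 0.36; 7 and 2 adjusted over the list alone; camera adjusted p = 0.204). Thbs2 lost its call without the experiment 3 or 4 library labelled p27-null (edgeR adjusted p up to 0.0692). Of 18 basement membrane genes 6 fell and 3 rose, also adjusted over the list alone (camera adjusted p = 0.610), with the laminin Lama4 (-4.87 ± 0.97) and the collagen Col18a1 (-3.01 ± 0.53) among the 6. Of 23 integrin and adhesion genes 7 fell and 4 rose (8 and 5 adjusted over the list alone; camera adjusted p = 0.683). Among them, cadherin Cdh13 was at -3.29 ± 0.37, the hyaluronan receptor Cd44 at 0.69 ± 0.12 and the laminin receptor subunit Itga6 at 1.33 ± 0.23 (edgeR adjusted p = 6.5e-05, 0.00118 and 0.00160); Cd44 and Itga6 lie on chromosome 2. Of 29 limb and positional transcription factors 4 rose and 5 fell (5 and 12 adjusted over the list alone; camera adjusted p = 0.746). Among them, Emx2 (2.11 ± 0.11) rose and Foxf1 (-3.41 ± 0.20) and Lhx9 (-4.21 ± 0.58) fell (edgeR adjusted p = 1.0e-07, 2.4e-07 and 0.000294). Of 8 neural and neural crest genes Tfap2a rose (2.59 ± 0.19; edgeR adjusted p = 1.6e-06) and 1 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.683). In all genes named in these paragraphs except Klf4, Thbs2 and Gli1 the 4 libraries labelled p27-null lay beyond all 8 wild-type libraries.

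Pseudogenes were more frequent among the large changes of the libraries labelled p27-null than among those that set a wild-type line apart. They made up 24 of the 533 genes called with at least a 4-fold change, or 4.50% (7 higher, 17 lower), against 3 of 496 (0.605%) and 2 of 691 (0.289%) for wild-type lines 1 and 2, each set against the other 2 lines. H2af-ps2, for example, was at 0.283 CPM against 84.7 and 109 CPM in wild-type lines 1 and 2, and Rps3a3 at 25.1 against 200.4 and 232. Against each wild-type line the share was 26 of 761 (3.42%) and 25 of 866 (2.89%), and between the wild-type lines 3 of 844 (0.356%); of the tested genes 7.30% were pseudogenes. Among genes with a mean of at least 5 CPM, pseudogenes made up 13 of the 222 large changes, or 5.86%, against 0 of 197 and 0 of 293 for the wild-type lines against the rest (Fisher's exact p = 2.1e-07), which argues against low counts as the whole cause. Under 5 CPM they made up 11 of 311, or 3.54%, against 3 of 299 (1.003%) and 2 of 398 (0.503%). Genes near the floor exclude nothing, so low counts stay open for these 11. Reads of near-identical coding genes that carry variants of another mouse strain could move counts between copies. Of pseudogenes with a near-identical coding transcript 21 of 953 changed, and of others 3 of 98 (odds ratio 0.714, 95% interval 0.207 to 3.81; Fisher's exact p = 0.484). The interval is too wide to decide and the strain of the lines is not given in the sources used here, so this stays open.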
